A study of Mus musculus with 9 samples.

How the data were processed

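RNA from whole liver of 5-week-old mice was sequenced in 9 libraries, 5 from control littermates (WT) and 4 from mice with OGT deleted, each named in the labels by genotype and replicate number. The design text gives a number of mice per group equal to the number of libraries, so each library was taken as a separate mouse. The sex and litter of each mouse, the batch, the library kit and the way in which OGT was deleted are not given in the sources used here.

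Per the submitters' processing notes, TopHat2 2.1.0 and HTSeq 0.9.1 were used with the mouse build mm10 (GRCm38). The authors deposited a table per library with a whole-number read count for each of 24421 gene symbols, without normalization, followed by 5 summary lines. The annotation release and whether counting used the strand are not given in the sources used here, so reads from a gene and a partner on the opposite strand cannot be told apart. The summary lines count separately the reads that align to more than a single place and those that overlap several genes, so neither entered a gene count. The summary lines stayed out of library sizes and tests. Reads outside annotated genes made up 8.95 to 10.7% of uniquely aligned reads, and reads that overlapped several genes 1.78 to 2.17%. Non-unique alignments numbered 7997176 to 35276937 per library and lie outside these shares. No gene of the mitochondrial genome is listed in the tables.

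Symbols were matched to GENCODE mouse release 21 (GRCm38), with 23376 matched directly and 668 through a synonym in RefSeq, and coordinates could be assigned to 24000 of the 24421 symbols. Coordinates are 1-based. The longest transcript of each named gene was split into all stretches of 50 bases, and the share of stretches also present in a transcript of another listed gene was recorded, as was the share of exonic bases that other listed genes cover on either strand. Genes with large shares are given as uncertain.

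Library totals were 32337861 to 54130901 counts assigned to genes, so that 3 counts correspond to 0.0554 to 0.0928 CPM. Within groups, 16 pairs of libraries were compared on genes with at least 10 counts summed over the pair. Chi-square per degree of freedom was 23.9 to 135.0, far above sampling noise, so no library was treated as a duplicate. Group differences in 7 library measures were tested with two-sided exact permutation tests, whose smallest possible p is 0.0159.

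Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr, scaled by trimmed mean of M-values (TMM) and tested with the quasi-likelihood F test (glmQLFit, glmQLFTest) on group alone, with Benjamini-Hochberg adjustment over all 14104 tested genes and a threshold of 0.05. CPM values use the TMM-scaled library sizes and a prior count of 2 enters the log2 values. The 46 gene lists were tested with camera and fry in limma 3.58.1. Camera used a preset correlation of 0.01, and was run again with the correlation estimated from the data. Both methods adjusted over the 45 lists with tested members. Lists of imprinted and of tubulin genes, written after the main fit was seen, were adjusted apart from the 45, over those lists alone. Principal components were taken from log2 CPM, and mean levels of cell type lists from log2 of CPM plus 0.1. Permutation tests used scipy 1.17.1, and figures matplotlib 3.10.9.

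The rule for named genes, written before the data were examined, took every tested gene of the O-GlcNAc and hexosamine list. It also took the 12 largest rises and 12 largest falls among genes with adjusted p under 0.05, mean CPM of at least 5 and no overlap between the groups, leaving out predicted or unnamed gene models. Finally it took up to 4 members of each list with the smallest p. Some genes that the rule took are not reported here. Genes outside the rule are identified as chosen after their values were seen. The lists, the main test and the alternatives were also fixed before the data were examined, except for 2 alternatives added later: leaving out the Mup gene family and leaving out the 30 most abundant genes.

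The alternatives were DESeq2 size factors and upper-quartile factors in place of TMM, no filter beyond a count above 0, a filter of CPM 1 in 4 libraries, DESeq2 1.42.0 (Wald test), limma voom, the replicate number as a block, the mean log2 CPM of Y chromosome genes as a covariate, and leaving out each library in turn. For comparison with chance, the gene test and the list test were repeated on 100 of the 126 possible splits of the 9 libraries into groups of 5 and 4, the real split included.

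The gene test was tested on simulated counts for 13396 genes, with the WT means for both groups and the library sizes of this comparison. Only the few genes counted below were changed, about equally upward and downward. A change as broad as the one called in the data was not simulated. Of genes changed by a log2 fold change of 2, 95.3% (61 of 64) were recovered, against 80.0% (52 of 65) at 1 and 36.9% (24 of 65) at 0.5, with median estimates of 1.97, 0.956 and 0.512. Unchanged genes made up 8.05% of the calls (12 genes), above the nominal 5%. The recovery at a log2 fold change of 1 fell short of the share first required of the simulation, more than 80%; the estimates there were close to the simulated values, and the requirement was relaxed. A list raised in the simulation was called with adjusted p = 6.34e-18, and 0 of the other lists were called. Counts were drawn independently for each gene, whereas list members in the data are correlated. This run therefore could not test for false list calls that such correlation causes.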

Results

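Gene expression was measured by RNA sequencing in whole liver from 5-week-old mice with O-GlcNAc transferase (OGT) deleted and from control littermates. The labels call the tissue of the former OGT-deficient liver. OGT is the enzyme that attaches the sugar N-acetylglucosamine to serine and threonine residues of nuclear and cytoplasmic proteins. The series held 5 control libraries (WT) and 4 libraries of OGT-deleted livers, and the mice had been without food for 6 h. Counts assigned to genes were 51444650, 54130901, 38958832, 32337861 and 36951396 in WT 1 to 5 and 38994976, 36323832, 45102080 and 37549730 in OGT-deficient 1 to 4. The group means of 42764728 ± 9506973 (SD, n = 5) and 39492655 ± 3895713 (SD, n = 4) did not differ in a two-sided exact permutation test (p = 0.508). A count of 1 corresponded to between 0.0185 and 0.0309 CPM, the count scaled to library size. A count above 0 was found for 15714 ± 263 genes per WT library and 16633 ± 220 genes per OGT-deficient library, and every OGT-deficient library lay above every WT library (exact permutation p = 0.0159, the smallest that 5 against 4 libraries allow, and 0.0222 after Benjamini-Hochberg adjustment over 7 library measures).

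The libraries also differed by group in reads that entered no gene count. Alignments to more than a single place numbered 16167401, 23901840, 24299437, 33109310 and 35276937 in the WT libraries and 7997176, 8129603, 9317390 and 8264277 in the OGT-deficient libraries (exact permutation p = 0.0159, adjusted 0.0222). Per read assigned to a gene this was 0.314 to 1.02 in WT and 0.205 to 0.224 in OGT-deficient liver. The 10 genes with the most counts over all libraries together held 17.3 ± 0.941% of the counts in WT and 15.5 ± 0.859% in OGT-deficient liver (exact permutation p = 0.0159, adjusted 0.0222). The series design describes mice of both sexes. Transcripts of the Y-linked gene Ddx3y were present at 77.3 to 91.1 CPM in all 5 WT libraries and at 55.4 to 60.9 CPM in all 4 OGT-deficient libraries, and Xist, which is transcribed from the inactive X chromosome, did not exceed 1.13 CPM (38 counts, in WT 5).

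**Figure D1:**
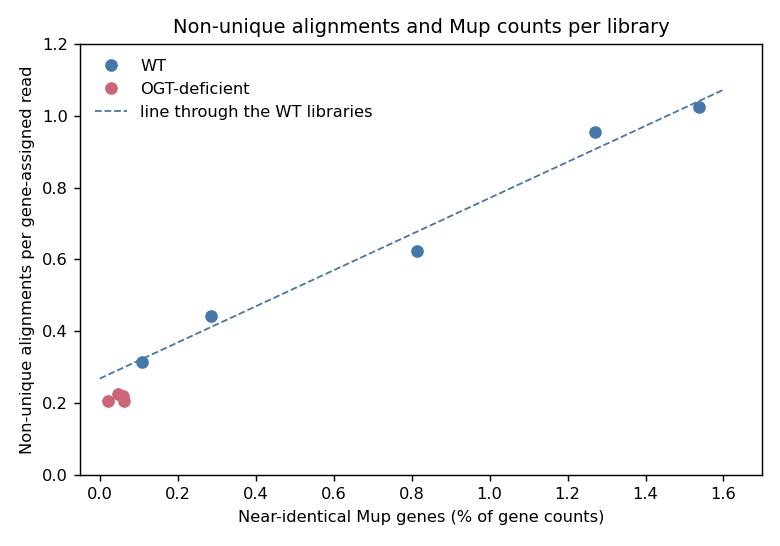
Non-unique alignments per gene-assigned read (vertical axis) against the percentage of gene counts in 14 near-identical Mup genes (horizontal axis), with a point per library and a dashed line fitted through the 5 WT libraries alone. The OGT-deficient libraries sit between 0.205 and 0.224 alignments per read, below the lowest WT library at 0.314.

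The comparison between the groups asks how loss of OGT changes gene expression in the liver. Ogt itself (chromosome X, 101640060 to 101684351, plus strand, GRCm38) measured 51.1, 54.2, 57.1, 73.1 and 72.3 CPM in WT 1 to 5 and 20.6, 14.3, 17.2 and 15.6 CPM in OGT-deficient 1 to 4. Its mean fell from 61.6 ± 10.4 CPM (SD, n = 5) to 16.9 ± 2.70 CPM (SD, n = 4), a log2 fold change of -1.86 (SE 0.14, adjusted p = 3.53e-07 in edgeR's quasi-likelihood test), so every library carried the change its label names. The labels do not say which part of the gene was deleted, and the counts cover the whole gene. The transcript of O-GlcNAcase, the enzyme that removes the same sugar (gene Oga, listed in the files as Mgea5; chromosome 19, 45750259 to 45783837, minus strand), fell from 75.0 ± 6.91 to 19.1 ± 1.82 CPM (log2 fold change -1.97, SE 0.10, adjusted p = 1.37e-08).

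The enzymes that make the donor sugar UDP-N-acetylglucosamine moved in both directions. Uap1l1, a relative of the last enzyme of the pathway, rose from 7.37 ± 1.77 to 62.6 ± 7.08 CPM, a log2 fold change of 3.08. Gfpt2 rose by 1.86 and Gfpt1, its relative at the entry to the pathway, by 0.47 on the log2 scale. Pgm3 rose by 0.67 and the salvage kinase Nagk by 0.54, while Uap1 fell by 0.65 and Gnpnat1 fell by 0.43. Gnpda2 (log2 fold change 0.20, adjusted p = 0.330), Eogt (0.07, adjusted p = 0.662) and Gnpda1 (-0.03, adjusted p = 0.832) did not pass the test. Of the 12 genes of the O-GlcNAc and hexosamine list, 5 rose and 4 fell. Ogt, the gene deleted by design, and Oga are among those that fell. As a set the list was not called by camera (adjusted p = 0.889). Genes on the opposite strand cover 81.9% of the exonic bases of Gnpnat1 and 28.3% of those of Pgm3, and 21.7% of the 50-base stretches of Gnpda1 occur in another listed gene, so these 3 values are uncertain.

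**Figure D2:**
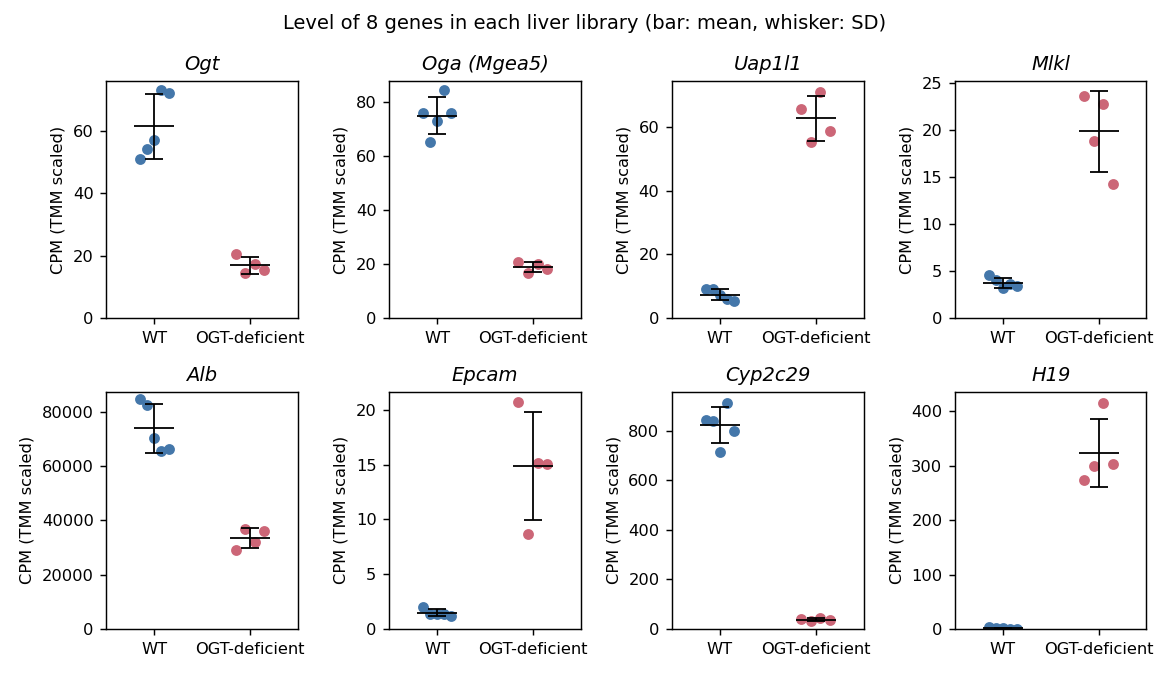
Level of 8 genes in CPM scaled by trimmed mean of M-values (vertical axes, from 0) in WT and OGT-deficient liver, with a point per library, a bar at the mean and whiskers of 1 SD. Ogt lies between 51.1 and 73.1 CPM in the 5 WT libraries and between 14.3 and 20.6 CPM in the 4 OGT-deficient libraries.

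Of 14104 genes tested, 8614 (61.1%) changed at an adjusted p under 0.05, with 4461 higher and 4153 lower in OGT-deficient liver. At least 2-fold changes numbered 2082 upward and 959 downward, and at least 4-fold changes 863 upward and 195 downward. The 4 OGT-deficient values lay wholly above or below the 5 WT values for 7232 genes (51.3%), where chance gives 1.59%. The first principal component of log2 CPM held 77.2% of the variance and separated the groups, and the next held 5.44%. The share of higher calls depended on the scaling: it was 51.8% as given and 62.5% of 8694 calls with upper-quartile factors, which placed the median log2 fold change of all genes at 0.145 in place of 0.0218.

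The largest rises among genes averaging at least 5 CPM reached genes with little expression in WT liver. H19, an imprinted noncoding RNA abundant in fetal liver (chromosome 7, 142575529 to 142578143), rose from 1.30 ± 1.25 to 323.5 ± 62.7 CPM, a log2 fold change of 7.87 (SE 0.47, and 8.63 without WT 1). The desmosomal protein gene Pkp1 rose by 7.01 on the log2 scale (SE 0.28), the neurotrophin receptor gene Ntrk2 by 5.92 (SE 0.40, and 6.68 without WT 3), the transporter gene Abcc12 by 5.59, the macrophage elastase gene Mmp12 by 5.57 and the tetraspanin gene Tspan8 by 5.31. Cbr3, a carbonyl reductase gene, rose by 5.02. The glypican gene Gpc3 rose by 4.80, the calcium pump gene Atp2b2 by 4.74 and the citrate transporter gene Slc13a5 by 4.62, from 1.35 ± 0.209 to 32.8 ± 3.01 CPM. Tubb2b, a beta-tubulin gene at 0.0683 ± 0.0722 CPM in WT and 19.2 ± 11.1 CPM in OGT-deficient liver, shares 39.3% of its 50-base stretches with other genes and is uncertain.

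The largest falls were led by Adgrf1, an adhesion receptor gene, which went from 16.0 ± 2.75 to 0.201 ± 0.114 CPM (log2 fold change -6.28, SE 0.28). Cyp2c29, a cytochrome P450 gene (chromosome 19, 39269405 to 39330713), fell from 822.5 ± 73.0 to 37.3 ± 5.30 CPM (log2 fold change -4.46, SE 0.13). The fatty acid hydroxylase gene Cyp4a14 went from 132.4 ± 166.5 to 5.56 ± 3.06 CPM (log2 fold change -4.56, SE 0.96, and -3.48 without WT 2) and the acyl-CoA thioesterase gene Acot3 from 9.61 ± 5.99 to 0.374 ± 0.501 CPM (log2 fold change -4.63, SE 0.77, and -6.15 without OGT-deficient 1). The sulfotransferase gene Sult5a1 fell by 4.57 on the log2 scale and the lipid droplet protein gene Fitm1 fell by 4.13. The major urinary protein genes Mup12, Mup1 and Mup7 (log2 fold changes -5.34, -5.09 and -4.92) share 85.4%, 94.8% and 88.4% of their 50-base stretches with other genes, and Cyp4a10 (-5.02) and Cyp4a32 (-4.63) share 30.5% and 46.8%, so these 5 values are uncertain.

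A set of 46 gene lists, drawn up before the data were examined, was tested with camera at a preset correlation of 0.01. The genes encoded by the mitochondrial genome are absent from the tables, which left 45 lists, of which 27 were called, 12 upward and 15 downward. None of the 27 was called by camera with an estimated correlation, where 3 of 45 lists had an unadjusted p under 0.05, and 17 of 100 splits of the libraries, the real one included, gave at least 27 called lists with the preset correlation. Fry, which asks whether members of a list change at all, called 31 of 45 lists by direction and 45 by change in either direction. It does not compare them with the other genes, as camera does. Because 61.1% of all tested genes were called, a fry call does not set a list apart from other genes. Counts of members adjusted over the list alone equalled those over all genes except where a separate count is given. Members named only because few members of their list went that way were chosen after their values were seen.

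Genes of the extracellular matrix and of scar-forming cells were higher in OGT-deficient liver. Of 32 fibrillar collagen and matrix genes 31 rose, with a median log2 fold change of 2.11, and only the fibronectin gene Fn1 fell, by 0.73 (camera adjusted p = 2.13e-08). Thbs1 rose by 2.85, the small proteoglycan gene Lum by 1.93 and Timp2, an inhibitor of matrix proteases, by 1.49 on the log2 scale. Col1a1, chosen after its values were seen, went from 18.8 ± 15.3 to 175.5 ± 42.1 CPM (log2 fold change 3.22, SE 0.44, and 3.82 without WT 1). Of 15 hepatic stellate cell and myofibroblast markers 12 rose and 0 fell (camera adjusted p = 0.000576), among them the smooth muscle actin gene Acta2 (1.52 ± 0.737 to 9.01 ± 1.98 CPM), Cygb and Tagln. With an estimated correlation, the matrix list had adjusted p = 0.345 and the stellate list adjusted p = 0.378.

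Markers of bile duct cells and recruited macrophages rose, while those of resident macrophages and endothelium did not move as sets. Of 15 cholangiocyte and ductular markers 13 rose and 1 fell, with a median log2 fold change of 3.33 (camera adjusted p = 0.000114). Epcam went from 1.46 ± 0.326 to 14.9 ± 4.91 CPM, Prom1 rose by 3.80 and Cldn7 by 4.48 on the log2 scale, and the keratin gene Krt19, chosen after its values were seen, rose by 3.33. Of 20 monocyte and recruited macrophage markers 16 rose and 0 fell (camera adjusted p = 1.75e-05), including Gpnmb (log2 fold change 5.01), Cd63 (4.25) and Cd9 (2.09). Both lists had adjusted p = 0.345 with an estimated correlation.

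Of 12 Kupffer cell markers, which mark resident liver macrophages, C1qa, C1qb and Marco rose and Cd163 and Slc40a1 fell; adjusted over the list alone 2 rose and 2 fell, and the set was not called (camera adjusted p = 0.916). Clec4f, chosen after its values were seen, stood at 172.7 ± 22 CPM in WT and 176.4 ± 37.3 CPM in OGT-deficient liver (log2 fold change 0.03, adjusted p = 0.861). Of 14 endothelial markers Vwf rose, and Clec4g, Gpr182, Oit3 and Stab2 fell (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.312). Lcn2, S100a8 and S100a9 rose among 6 neutrophil markers (camera adjusted p = 0.185). Camera adjusted p was 0.983 with the Y chromosome covariate and 0.716 with an estimated correlation. Over the other alternatives it was 0.0125 to 0.290, the lowest without OGT-deficient 4. Fry called the neutrophil list upward with adjusted p = 0.0241. Gzmb fell among 15 T and NK cell markers (0 adjusted over the list alone, camera adjusted p = 0.757). Cd74 and Jchain rose and 2 genes including Blk fell in the list of 10 B and plasma cell markers (1 rose and 0 fell adjusted over the list alone, camera adjusted p = 0.730), and Car2 rose and Klf1 fell among 4 erythroid genes (camera adjusted p = 0.800).

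**Figure D3:**
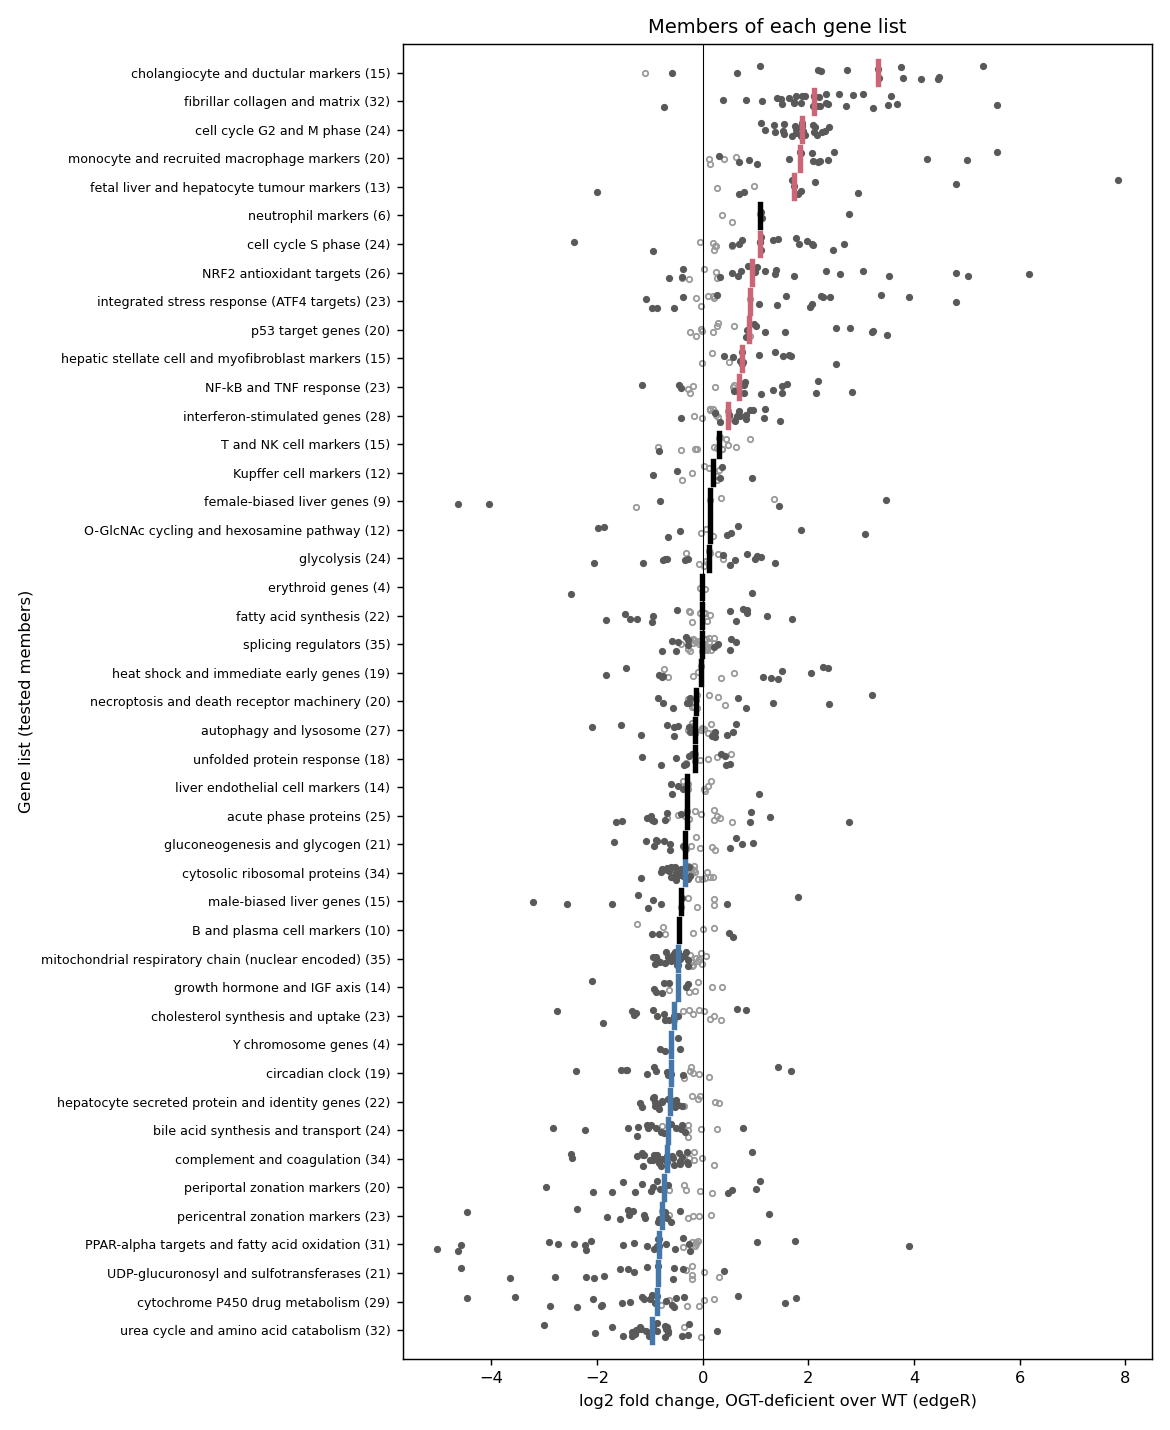
Log2 fold change of each tested member (horizontal axis) of the gene lists (vertical axis, with the number of tested members), ordered by the list's median. Filled points passed the edgeR test, open points did not, and the vertical bar is the median, red for the 12 lists called upward by camera, blue for the 15 called downward and black for the rest; the medians run from -0.96 for urea cycle and amino acid catabolism to 3.33 for cholangiocyte markers.

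Cell cycle genes rose in the same libraries. All 24 tested genes of the G2 and M phases rose, with a median log2 fold change of 1.87 (camera adjusted p = 4.44e-06), among them the topoisomerase gene Top2a (4.89 ± 1.89 to 18.5 ± 2.08 CPM), the mitotic kinesin gene Kif11 and the kinase gene Cdk1. Of 24 S phase genes 16 rose, 17 adjusted over the list alone, including the replicative helicase gene Mcm6 (log2 fold change 2.68) and the ribonucleotide reductase gene Rrm1 (1.09), while Ccne1 and Tk1 fell by 2.44 and 0.95 (camera adjusted p = 0.000367). The G2 and M list had adjusted p = 0.507 and the S phase list adjusted p = 0.345 with an estimated correlation. Of 13 fetal liver and hepatocyte tumour markers 10 rose, among them H19, Gpc3 and the alpha-fetoprotein gene Afp (2.83 ± 0.483 to 12.5 ± 2.22 CPM), and Tff3 fell by 2.01 (camera adjusted p = 0.000940; adjusted p = 0.345 with an estimated correlation).

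Stress response lists rose in part. Of 20 p53 target genes 11 rose and 0 fell (camera adjusted p = 0.000887), among them Phlda3 (log2 fold change 3.22), the death receptor gene Tnfrsf10b (3.20) and the cell cycle inhibitor gene Cdkn1a (2.80). Of 26 NRF2 antioxidant targets 18 rose and Gclm, Prdx1 and Taldo1 fell, against 19 and 4 adjusted over the list alone (camera adjusted p = 0.000703); the sulfiredoxin gene Srxn1 went from 43.0 ± 3.26 to 262.1 ± 63.3 CPM, and Pgd and Gstm4 rose by 1.73 and 1.36 on the log2 scale. Both lists had adjusted p = 0.345 with an estimated correlation. Of 23 integrated stress response genes 12 rose, including the hormone gene Fgf21 (log2 fold change 3.91), the serine synthesis gene Phgdh (3.37) and the folate cycle gene Mthfd2 (2.24). The 5 that fell were Atf4, which encodes the transcription factor of this response, the asparagine synthetase gene Asns, Cebpb, Shmt2 and Trib3. The list had camera adjusted p = 0.0265. Over the alternatives other than the Y chromosome covariate this was 0.0167 to 0.0509, the highest with upper-quartile factors. The list had adjusted p = 0.146 with that covariate and adjusted p = 0.345 with an estimated correlation.

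Inflammatory genes rose as follows. Of 23 NF-kB and TNF response genes 13 rose, among them the chemokine gene Ccl2 (log2 fold change 2.19) and the adhesion molecule genes Vcam1 (1.33) and Icam1 (0.79), and Cxcl1, Nfkbia and Sod2 fell. The list had camera adjusted p = 0.0286, 0.0176 to 0.0995 over the alternatives, and lost its call with upper-quartile factors and with a filter of CPM 1 in 4 libraries (0.0995); adjusted p = 0.507 with an estimated correlation. Of 28 interferon-stimulated genes 15 rose, among them the immunoproteasome genes Psmb9 (1.47) and Psmb8 (1.16), and Irf9 fell (camera adjusted p = 0.00530; adjusted p = 0.520 with an estimated correlation). The recruited macrophage markers given above rose in the same libraries.

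Among 20 genes of necroptosis and death receptor signalling, Mlkl, Tnfrsf10b, Zbp1, Bax and Tnfaip3 rose and 6 fell, among them the adaptor gene Fadd (log2 fold change -0.85). Mlkl, which encodes the membrane-permeabilising effector of necroptosis, went from 3.78 ± 0.549 to 19.9 ± 4.31 CPM (log2 fold change 2.39, SE 0.16, adjusted p = 1.37e-07), and Zbp1 from 6.25 ± 0.921 to 15.8 ± 3.71 CPM. Ripk3, the kinase upstream of MLKL and chosen after its values were seen, stood at 1.90 ± 0.457 and 2.58 ± 0.806 CPM (log2 fold change 0.43, adjusted p = 0.159). Over the alternatives other than the Y chromosome covariate, its adjusted p was 0.0344 to 0.384, the lowest without OGT-deficient 4. With that covariate it was 0.972. The list was not called (camera adjusted p = 0.889), and its median of -0.12 and mean of 0.27 differ in sign.

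Genes of hepatocyte identity and secretion fell in the libraries in which bile duct, stellate and recruited macrophage markers rose. Of 22 hepatocyte secreted protein and identity genes 16 fell and 0 rose (camera adjusted p = 0.000420): the albumin gene Alb went from 73880 ± 9066 to 33491 ± 3673 CPM, and the apolipoprotein gene Apoa1 fell by 1.18 on the log2 scale. Of 34 complement and coagulation genes 28 fell, 29 adjusted over the list alone, and the lectin gene Mbl2 rose (camera adjusted p = 3.19e-07). Factor XI (F11) fell by 2.49, plasma kallikrein (Klkb1) fell by 2.48 and antithrombin (Serpinc1, 34.4% of whose exonic bases another gene covers) fell by 1.12 on the log2 scale. Both lists had adjusted p = 0.345 with an estimated correlation.

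Transcripts of the lists for amino acid catabolism, fatty acid oxidation, bile acids and cholesterol were mostly lower. Of 32 urea cycle and amino acid catabolism genes 29 fell and Cth rose by 0.27 (camera adjusted p = 3.93e-09). The falls included Prodh2, which acts on hydroxyproline (228.1 ± 12.4 to 28.4 ± 2.91 CPM), and Hal (log2 fold change -1.71). Of 31 PPAR-alpha targets and fatty acid oxidation genes 22 fell (camera adjusted p = 2.29e-05), including Etfdh (-2.74), Ehhadh (-2.23) and Fabp1 (-2.11), while Fgf21, Pdk4 and Cd36 rose. Of 24 bile acid genes 16 fell and Abcb4 rose (camera adjusted p = 0.000207); the uptake carrier gene Slc10a1 went from 737.0 ± 38.5 to 317.8 ± 40.5 CPM, Slc27a5 fell by 1.24 and the FGF receptor gene Fgfr4 fell by 2.23 on the log2 scale. These 3 lists had adjusted p = 0.345 with an estimated correlation. Of 23 cholesterol synthesis and uptake genes 12 fell, among them Hsd17b7 (-2.76), Stard4 (-1.89) and Insig1 (-0.93), and 2 rose, Mvd among them (camera adjusted p = 0.0176). Over the alternatives other than the Y chromosome covariate this p was 0.00331 to 0.0787, the highest without OGT-deficient 1. The cholesterol list had adjusted p = 0.327 with that covariate and adjusted p = 0.780 with an estimated correlation.

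Drug metabolism and zonation markers fell too. Of 29 cytochrome P450 genes 20 fell, with Cyp2e1 going from 8028 ± 875 to 1551 ± 212 CPM and Cyp2f2 from 1391 ± 212 to 332.5 ± 16.1 CPM, and Cyp2c67, Cyp3a11 and Cyp3a59 rose (camera adjusted p = 0.000105); Cyp2c67 and Cyp3a59 share 52.8% and 28.0% of their 50-base stretches with other genes and are uncertain. Of 21 UDP-glucuronosyl and sulfotransferase genes 14 fell (camera adjusted p = 0.000197), among them Ugt3a1 (log2 fold change -3.64) and Ugt1a1 (-2.05), and Ugt1a6a rose (0.41). Ugt1a1 and Ugt1a6a have 59.0% and 50.3% of their exonic bases covered by other genes of their family and are uncertain. Of 23 pericentral markers 16 fell, Rgn among them (-1.57), and Slc13a3 rose (camera adjusted p = 2.40e-05). Of 20 periportal markers 11 fell, Uroc1 among them (-1.50), and Aldh1b1, Cdh1, Etnppl and Hsd17b13 rose, against 12 and 5 adjusted over the list alone (camera adjusted p = 0.0136). The 4 lists had adjusted p = 0.345 with an estimated correlation.

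Respiratory chain, ribosomal, clock and growth hormone genes were lower. Of 35 nuclear-encoded respiratory chain genes 25 fell and 0 rose, 26 adjusted over the list alone, with Sdhb at -0.89 and Uqcrfs1 at -0.86 (camera adjusted p = 1.99e-06). Of 34 cytosolic ribosomal protein genes 20 fell and 0 rose, Rplp1 by 1.17 and Rps2, which shares 11.6% of its stretches with other genes, by 0.76 (camera adjusted p = 0.000105). Of 19 clock genes 11 fell, among them Per3 (-1.55), Dbp (-1.45) and Hlf (-1.42), and Arntl (1.44) and Npas2 (1.67) rose (camera adjusted p = 0.0129). Of 14 genes of the growth hormone and IGF axis 8 fell and 0 rose: Igfals went from 175.7 ± 20.5 to 41.3 ± 14.4 CPM, Ghr fell by 0.88 and Igf1 fell by 0.64 on the log2 scale (camera adjusted p = 0.0236). With an estimated correlation the ribosomal list had adjusted p = 0.520 and the other 3 lists adjusted p = 0.345.

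Sex-linked and sex-biased genes were included because the design names both sexes. All 4 tested Y chromosome genes, Ddx3y, Eif2s3y, Kdm5d and Uty, fell, Ddx3y from 82.3 ± 5.64 to 59.3 ± 2.64 CPM (camera adjusted p = 0.0236; adjusted p = 0.345 with an estimated correlation). Of 15 male-biased liver genes 8 fell, among them Ces3b (log2 fold change -2.56) and Hsd3b5 (-1.72), and Elovl3 and Mup20 rose. The list was not called at camera adjusted p = 0.0813, but 5 of 16 alternatives of scaling, filter, block or left-out genes and libraries called it, over a range of 0.0310 to 0.140, and fry called it downward (adjusted p = 0.0278). Mup20, chosen after its values were seen and sharing 4.66% of its stretches with other genes, went from 6129 ± 3941 to 21464 ± 3549 CPM. Among 9 female-biased genes Cyp2a4 and Cyp3a44 rose and Acot3, Cyp17a1 and Cyp2c69 fell, against 1 and 3 adjusted over the list alone (camera adjusted p = 0.994), and the median of 0.15 and mean of -0.44 differ in sign. Shared stretches make up 26.1% of Ces3b, 18.7% of Hsd3b5, 36.1% of Cyp2a4, 18.2% of Cyp3a44 and 54.8% of Cyp2c69, which are uncertain. With the mean level of the Y chromosome genes as a covariate, 180 genes were called, 175 of them main calls kept with their direction. Ogt stood at -0.90 (adjusted p = 0.361). That level of the Y chromosome genes was 5.00 to 5.23 log2 CPM in WT and 4.35 to 4.54 in OGT-deficient libraries, so the covariate follows the group.

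The remaining lists were not called as sets by camera. Among 18 unfolded protein response genes Dnajb11, Pdia4, Pdia6 and Sdf2l1 rose and 7 fell, Herpud1 among them (camera adjusted p = 0.516). Among 25 acute phase genes Lcn2, Steap4, Orm2 and Mt2 rose and 9 fell, Saa4 by 1.64 (camera adjusted p = 0.312). Among 21 genes of gluconeogenesis and glycogen, 4 rose, among them Gbe1, Ugp2 and Ppargc1a. In the same list 10 fell, including the alanine aminotransferase gene Gpt (log2 fold change -1.67) and the glucose-6-phosphate carrier gene Slc37a4 (-0.92). Camera did not call this list (adjusted p = 0.166), but fry called it downward (adjusted p = 0.00332). Among 24 glycolysis genes 8 rose, Gpi1 by 1.03, and 7 fell, Pklr by 2.05 (camera adjusted p = 0.994); fry gave this list and the O-GlcNAc list a downward direction where camera gave an upward sign. Among 22 fatty acid synthesis genes 7 rose, Acaca by 0.84, and 7 fell, Acss2 by 1.46 (camera adjusted p = 0.730). Among 35 splicing regulators 5 rose, among them Hnrnph1, Sf3a1, Tra2a and Tra2b, and 7 fell, Luc7l2 and Rbm39 among them (camera adjusted p = 0.655). Among 19 heat shock and immediate early genes 7 rose, 8 adjusted over the list alone, Hspb1 by 2.37, and Dnajb1, Hsph1, Egr1, Hspa8 and Ier2 fell (camera adjusted p = 0.779; median -0.04 and mean 0.30). Among 27 autophagy and lysosome genes 6 rose and 9 fell, Wipi1 (log2 fold change -2.10) and Lamp2 (-0.67) among them (camera adjusted p = 0.348, but called downward by fry with adjusted p = 0.00379). Genes on the opposite strand cover 18.0% of the exonic bases of Dbp, 20.7% of Cebpb, 21.97% of Pklr and 14.9% of Gnpda2, and Orm2 shares 21.8% of its 50-base stretches with another gene, so these 5 values are uncertain.

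Of the 215 genes named in the text, 210 passed the edgeR test. For 180 of these the OGT-deficient libraries lay wholly above or below the WT libraries. Most were named because of these same test results, so both counts largely follow from the choice of genes. Of the 210, 21 lost their call under at least 1 alternative other than the Y covariate, with adjusted p up to 0.164; these were Asns, Blk, C1qa, C1qb, Cth, Cyp17a1, Cyp3a44, Elovl3, Gpr182, Gzmb, Jchain, Marco, Npas2, Oit3, Pdia4, Ppargc1a, S100a8, S100a9, Sdf2l1, Stab2 and Tra2b. For 3 of these a single alternative ended the call: Marco (adjusted p = 0.0735 without OGT-deficient 2, with a range of 0.000757 to 0.0735), Cth (0.0626 without OGT-deficient 2, range 0.00206 to 0.0626) and Elovl3 (0.0545 without OGT-deficient 2, range 0.00279 to 0.0545).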

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

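Within each group, the highest and lowest library of every named gene and of 6 library measures was compared with the rest, in 442 comparisons, and 26 values of single libraries stood apart by Dixon's criterion at the 95% level. Chance alone gives about 5%, so the number of such values is close to that of chance. No explanation was tested for single libraries.

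Among the WT libraries, WT 1 stood above the others for Marco, a macrophage receptor gene (20.2 against 8.17 to 10.1 CPM), the bile duct marker Epcam (2.03 against 1.19 to 1.39 CPM), Atp2b2 (3.80 against 0.902 to 1.599 CPM) and Mthfd2 (1.88 against 1.25 to 1.37 CPM), and below them for the splicing regulator Tra2a (8.78 against 12.5 to 12.96 CPM). WT 3 stood above the others for Ntrk2 (2.64 against 0.243 to 0.805 CPM), Cygb (13.4 against 9.12 to 10.3 CPM), the liver pyruvate kinase gene Pklr (827.0 against 445.6 to 514.5 CPM) and Tff3 (15.9 against 6.53 to 8.64 CPM), and below them for Mbl2 (235.1 against 271.3 to 281.4 CPM). WT 2 was above the others for Serpinc1 (2727 against 2375 to 2450 CPM) and below them for Cebpb (74.7 against 129.5 to 136.6 CPM). WT 4 was above for Tk1 (47.0 against 35.4 to 36.9 CPM) and WT 5 for the imprinted noncoding RNA gene Rian (2.32 against 0.451 to 0.982 CPM).

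Among the OGT-deficient libraries, OGT-deficient 1 stood above the others for Mmp12 (24.9 against 12.9 to 14.2 CPM), Acot3 (1.12 against 0.0504 to 0.229 CPM) and Timp2 (44.2 against 35.2 to 36.0 CPM). OGT-deficient 2 was above for Cd163 (21.6 against 10.1 to 11.5 CPM), Asns (2.42 against 0.686 to 0.930 CPM) and the phospholyase gene Etnppl (475.1 against 371.2 to 387.2 CPM). OGT-deficient 3 was above for Cyp4a14 (10.1 against 3.70 to 4.53 CPM), Rrm1 (31.8 against 29.2 to 29.5 CPM) and the phosphofructokinase gene Pfkm (17.0 against 13.4 to 13.8 CPM), and below for Ddx3y (55.4 against 60.3 to 60.9 CPM). OGT-deficient 4 was above for Cyp17a1 (5.97 against 3.30 to 3.41 CPM) and below for the calprotectin gene S100a9 (0.930 against 2.90 to 3.25 CPM).

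In data outside the gene counts, uniquely aligned reads that fell in no annotated gene made up 10.3 ± 0.367% of uniquely aligned reads in OGT-deficient liver (SD, n = 4) and 9.41 ± 0.396% in WT liver (SD, n = 5), and every OGT-deficient library lay above every WT library (two-sided exact permutation p = 0.0159, adjusted 0.0222 over 7 library measures).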

How the results depend on the processing

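The 2 alternatives that leave out genes (the Mup family and the 30 most abundant genes) were chosen after seeing the data. Over the changes of scaling, filter and tool, the added alternatives and the block, between 7869 and 8985 genes were called against 8614, and between 26 and 28 lists by camera against 27. Leaving out each library in turn gave 7960 (without OGT-deficient 3) to 8472 (without WT 1) genes, log2 fold changes of -1.98 to -1.79 for Ogt and 26 to 28 lists. No called gene changed sign in any of these fits. With camera's estimated correlation 0 lists were called (3 with an unadjusted p under 0.05), against 27 with the preset one and 31 with fry; the estimates ran from 0.0118 to 0.856, the setting also changes the degrees of freedom, and the cause was not tested. The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.052, -0.103, 0.022 and 0.104 across genes, with 1 of 4 highest for its own number, and with the replicate number as a block 7869 genes and 27 lists were called. Lists that lost a call elsewhere are given beside their results.

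With the mean level of the Y chromosome genes as a covariate, 180 genes and 15 lists were called. Of these, 175 genes and 14 lists were main calls kept with their direction. Ogt had a log2 fold change of -0.90 (adjusted p = 0.361). The covariate is lower in every OGT-deficient library than in every WT library, so it follows the group; the cause of the lost calls was not tested. Under it, of 214 named genes besides Ogt, 160 kept their sign but lost the call and 31 reversed, none of them called: Nagk -0.22, Gnpnat1 0.60, Vwf -0.40, Top2a -0.38, Kif11 -0.074, Per3 0.24, Ddx3y 0.11, Col1a1 -0.58, Gclm 0.010, Atf4 0.16, Nfkbia 0.16, Cyp3a11 -0.093, Slc13a3 -0.074, Aldh1b1 -0.21, Arntl -0.51, Npas2 -4.36, C1qa -0.44, C1qb -0.38, S100a8 -0.17, S100a9 -0.13, Car2 -0.79, Pdia4 -0.44, Pdia6 -0.29, Sdf2l1 -0.80, Mt2 -0.81, Orm2 -1.93, Cyp3a44 -1.08, Cyp17a1 1.34, Kdm5d 0.21, Uty 0.49 and Clec4f -0.38 (log2 fold changes). Of the lists, 11 reversed without a call: G2 and M phase (adjusted p = 0.0608), clock (0.479), Y chromosome (0.756), necroptosis (0.174), Kupffer (0.286), T and NK cell (0.773), gluconeogenesis (0.286), glycolysis (0.479), splicing (0.366), male-biased (0.983) and heat shock (0.756). At a log2 fold change of 0.5 the simulation recovered 36.9% of changed genes at the depth, spread and number of libraries of this comparison, whose parts in this were not tested. Levels under 0.0554 to 0.0928 CPM rest on fewer than 3 counts in a library.

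Elsewhere only results called under neither setting changed direction, and the cause was not tested. For genes (log2 fold changes), Gnpda1 reversed with upper-quartile factors (0.09), the CPM 1 filter (0.0005) and the replicate block (0.0074), and Clec4f with the block (-0.0216); leaving out a library gave -0.1295 to 0.0093 for Gnpda1, -0.115 to 0.121 for Clec4f and -0.0007 to 0.110 for Eogt. For lists (adjusted p), these were the female-biased list with DESeq2 size factors (0.9987), glycolysis (0.995) and heat shock (0.9963) with upper-quartile factors, Kupffer (0.9639), glycolysis (0.8837) and female-biased (0.9553) without a filter, necroptosis (0.9674) and B and plasma cell (0.6399) with the CPM 1 filter, Kupffer with the replicate block (0.9747), the O-GlcNAc list (0.431), necroptosis (0.1439) and glycolysis (0.177) with fry, and glycolysis (0.9553) and female-biased (0.9617) without the 30 most abundant genes. Leaving out a library gave adjusted p of 0.5311 to 0.978 for Kupffer, 0.6777 to 0.9319 for erythroid, 0.7864 to 0.978 for female-biased, 0.9163 to 0.9943 for glycolysis and 0.8013 to 0.9837 for necroptosis, each with a reversed direction in at least 1 fit.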

Other observations

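The lists of imprinted and of tubulin genes, the line through the WT libraries, the comparison of cell type markers, the check of sex and the removal of the 30 most abundant genes were tests chosen after results had been seen; the splits of the libraries and the test of GC content and length were planned.

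Imprinted genes other than H19 were raised in OGT-deficient liver; those named here, and the tubulin genes below, were chosen after their values were seen. The noncoding RNA genes Rian and Meg3 of the Dlk1 locus rose by 3.84 and 2.89 on the log2 scale and the retrotransposon-derived gene Peg10 by 3.92, and the fetal growth factor gene Igf2 went from 0.431 ± 0.0788 CPM (SD, n = 5) to 1.51 ± 0.310 CPM (SD, n = 4). Of 18 further imprinted genes tested, leaving out H19, Rian and Peg10, 8 rose, 1 (Slc22a18) fell and 9 did not pass, with a median log2 fold change of 0.79 (camera adjusted p = 0.0033; adjusted p = 0.0603 with an estimated correlation). Impact (log2 fold change 1.99) was among those that rose, as were Igf2 and Peg3 (0.70), which are also in the fetal liver list. The hypothesis that the imprinted network rises as a whole predicted that most of the 18 would rise; 8 did, which leaves it undecided.

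Tubulin genes rose as well. Tubb2a went from 17.8 ± 5.17 CPM (SD, n = 5) to 383.3 ± 106.8 CPM (SD, n = 4; log2 fold change 4.42), although 49.6% of its 50-base stretches occur in other genes, and Tubb2b rose from near absence. Of 22 other tubulin and microtubule genes 15 rose and 0 fell. Among those that rose were Tuba8 (log2 fold change 2.95), Tubb4b (1.42) and Tuba1b (1.32). The median log2 fold change of the 22 was 0.57 (camera adjusted p = 0.00012, and adjusted p = 0.0603 with an estimated correlation). Both p values were adjusted over the imprinted and tubulin lists alone. A coordinated rise of tubulin and microtubule genes is therefore a hypothesis that these 15 of 22 members meet. The 22 include microtubule genes that are not tubulins, so the count is not of tubulins alone. Of all 14104 tested genes, 4461 rose. A further reservation is that 65.2% of the stretches of Tuba1b are shared with other genes.

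The number of changed genes, 8614, exceeded that of every other split of the libraries tried. Only 1 of 100 splits, the real one, gave as many, a share of 0.01, and the highest other gave 3923. The split with 3923 placed 1 WT library in its first group, so it kept most of the group difference. Every split but the real one mixes genotypes within a group, so its count does not show what groups without a difference would give. Chance is thus unlikely for the count of changed genes but is not excluded. For the number of called lists, 17 of 100 splits gave at least 27 and the highest other gave 31. Splits that divide the WT libraries unevenly keep part of the group difference, so their counts are not those of chance alone. Whether chance accounts for the number of called lists therefore stays undecided. GC content and exonic length explained little of the fold changes (R2 = 0.00227 over 14001 genes). This argues against them as the main cause of the gene count. Without the 30 most abundant genes, 98.2% of the calls were kept with their direction. TMM trims the most abundant genes before it sets the scaling, so this removal could hardly change the calls and cannot decide about scaling. With upper-quartile factors, 7720 of the 8614 calls were kept with their direction. The labels give no batch, so a batch that follows the genotype could not be tested. A difference in sex is argued against by Y transcripts in all libraries, with over 10 times as much Ddx3y (55.4 to 91.1 CPM) as Xist (at most 1.13 CPM) in 9 of 9, while the genotype stays open as the biological explanation, as does litter, which the labels do not give per mouse.

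Non-unique alignments were fewer in every OGT-deficient library, and near-identical Mup genes are a candidate source. A line of non-unique alignments per gene read on the share of counts in 14 near-identical Mup genes of 20, drawn through the 5 WT libraries, had a slope of 0.503 per percent and an intercept of 0.268. The observed values of all 4 OGT-deficient libraries lay inside its 95% prediction interval, although each was below the predicted value (0.278 to 0.299 predicted, 0.205 to 0.224 observed). The interval is wide (from 0.0922 to 0.483 over the 4 libraries) and reaches above the lowest WT library at 0.314, so these values neither exclude nor support reads shared between Mup paralogs. The genotype stays open as well.

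Markers of several cell types rose in OGT-deficient liver, and a lower share of hepatocytes in the tissue is a candidate explanation. Mean log2 CPM of the cholangiocyte list was 2.46 higher, that of the recruited macrophage list 1.83 higher and that of the stellate list 0.98 higher, against 0.04 for the Kupffer list and -0.18 for the endothelial list (two-sided exact permutation p = 0.0159, 0.0159, 0.0159, 0.857 and 0.492). The rise of cholangiocyte over endothelial markers was 2.64 (pooled SD 0.421). This pair was picked after the values were seen, as the largest and smallest change among these lists. A lower share of hepatocytes, with expression within the other cells unchanged, would raise both alike. The values argue against that as the whole cause. Of the markers, 1 of 15 cholangiocyte and 2 of 20 macrophage genes are also in another list, and 9 and 14 of them averaged at least 1 CPM in WT liver. More cells of the types that rose, or higher expression within cells, remain open and cannot be separated in whole tissue.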
